A study of Mus musculus with 12 samples.

How the data were processed

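The deposited files hold the Agilent Feature Extraction output of each array. Per the file headers, the intensity of each of 62976 spots was background-subtracted, corrected and scaled by Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12), whereas the notes of the authors name version 10.7.3.1. The authors deposited a second table of log2 values, in which each array's 75th percentile was subtracted from the log2 of its processed signal without centring by gene. That table and the log2 signal differed by a single constant per array, with an SD of 0.00365 to 0.00640 around it. The 75th percentile of signal was 126 to 138 on the day 0 organoid arrays and 201 to 287 on the others, and no spot was saturated.

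From the processed signal, the log2 was taken and each array's 75th percentile subtracted. Between 108 and 206 outlier spots per array were left out. Of 55681 probes, 28026 were named by accession, 3418 by symbol and 295 by synonym against a table of 49997 genes, 5037 kept the name of the file and 18905 had none. Where a gene had several probes (7364 symbols), the probe with the highest mean over the 12 arrays was kept, which left 27286 symbols, 14 of them with a missing value. Genes were tested where the signal was well above background on every array of at least 1 group, or on at least 1 array for the stage trend and for comparisons of 1 array with 1 array.

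Groups were compared with limma 3.58.1 under R 4.3.3, with the package data.table (1.17.8), Python 3.11.15 and matplotlib 3.10.9. Moderated t-tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The organoid groups were fitted alone on 6 arrays. Comparisons with kidney came from a fit of 4 groups on 8 arrays, in which the lone kidney arrays were assumed to vary like organoid replicates. The stage trend was a slope over 5 stages with 1 array each. For each of 25 lists camera was run with a preset correlation of 0.01 between genes, and again with an estimated correlation. Pairs of 1 array were compared without a test, and their lists were set against 10000 random lists matched on signal. A fold was given as at least a value where a group was below background on all its arrays, and differences of changes were limited in the same way.

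The lists, the groups, the tests, the naming rule and most alternatives were chosen before the data were examined. The 8 genes with the largest change each way were named for organoids and the stage trend, and 5 each way for other comparisons. They had to have a symbol and, where tested, pass the threshold, not overlap in the replicated groups and be well above background in the brighter group. Some genes that met this rule are not reported here and were left out of the genes followed under the alternatives. Trend genes had to change the same way at all 4 steps. Up to 4 members with the largest change were drawn on per list. The alternatives planned were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the authors' table, the mean of probes, other background filters, moderation with trend and robust settings, a fold threshold, a block for replicate number and leaving out each array. With replicate number as a block, 4602 genes rose and 6561 fell between day 0 and day 7. Slide as a block in comparisons with kidney, single slides and subtraction of a P0-like signal were added after the data were seen. Recovery was measured on simulated changes in 100 genes per comparison and size. Genes were simulated independently and without a slide effect, and lone kidney arrays were given the spread of organoid replicates. The counts of false calls therefore do not test these assumptions.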

Results

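RNA of mouse kidney tissue was measured on 12 one-colour Agilent arrays. Fresh kidneys came from the embryonic stages E11.5, E13.5, E15.5 and E17.5, named by days after conception, and from the day of birth (P0), with 1 array per stage. A sixth kidney array came from E11.5 kidney kept in culture for 7 days. The other 6 arrays came from organoids, which were built by mixing nephron progenitors and ureteric bud made from mouse embryonic stem cells with stromal progenitors of E11.5 kidney. Organoids were measured before culture (day 0, n = 3) and after 7 days of culture (day 7, n = 3). Between 50.6% and 54.3% of the 55681 probes were well above background on the day 0 arrays, and 56.1% to 63.3% on the others. The number of arrays limits the precision, and kidney groups have no replicates. The labels do not say that organoid replicates were separate cultures, so each p-value measures only the spread between these arrays. The kidney arrays and day 0 replicates 1 and 2 shared 1 slide, while day 0 replicate 3 and the day 7 arrays shared another. Differences are log2 values ± the standard error of the fitted model, and a gene rose or fell where limma gave an adjusted p under 0.05 (two-sided).

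The first question was what changed while organoids were cultured for 7 days. Day 7 organoids had far more RNA of mature nephron and collecting duct cells, of contractile and matrix-forming stroma and of vessels, and far less of embryonic globins, neuronal genes and cortical stromal progenitors. By list these calls rest on a preset correlation, and none held with an estimated correlation (adjusted p = 0.188 to 0.324 with an estimated correlation), while 1 other split of the 6 arrays also gave 16 list calls. Large rises were seen for Igfbp1 (10.18 ± 0.37, at least 377-fold), which encodes a binding protein of insulin-like growth factors, and Krt23 (9.24 ± 0.11, at least 139-fold), an epithelial keratin. Ltbp2 (8.44 ± 0.34), a matrix protein, and Ankrd1 (8.25 ± 0.15, at least 70.3-fold), a nuclear ankyrin-repeat protein of muscle and wounded tissue, followed. Clec18a, a kidney lectin, rose 161-fold (7.33 ± 0.29). Rnf186 (7.56 ± 0.40, at least 69.6-fold) and Glipr1 (7.34 ± 0.30, at least 66.2-fold) also rose. The embryonic globin Hbb-y fell at least 502-fold (-9.86 ± 0.22), and Hba-x (-6.86 ± 0.10), Hba-a1 (-6.26 ± 0.95) and Hba-a2 (-5.93 ± 0.97) fell with it. Chl1 (-8.24 ± 0.73), a neural adhesion molecule, Gfra3 (-7.73 ± 0.12, 212-fold), the receptor of artemin, Lin28b (-7.15 ± 0.40, at least 70.9-fold), an RNA-binding protein of early embryos, and Crabp1 (-6.47 ± 0.26, 88.5-fold), a retinoic acid binding protein, fell as well. In total 4953 genes rose and 7401 fell of 17998 tested, and 2833 and 1654 of these changed at least 2-fold. The median of all genes was -0.17, so many falls were small. The higher share of calls was 40.1%, but 29.6% without a background filter and 63.1% at a 2-fold threshold. The balance of rises and falls therefore depends on the setting. The values of the 2 organoid groups did not overlap for 13483 genes (74.9%, where chance gives 10%), and 12266 of the called genes were among them.

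All 13 members of the early nephron list, which marks renal vesicles and S-shaped bodies, rose, among them Hes5 (4.70 ± 0.17, 25.9-fold), a Notch target, Wnt4 (3.78 ± 0.16, 13.8-fold), the inducer of epithelial conversion, and the Notch ligand Jag1 (3.47 ± 0.10, 11.1-fold). Its median change was 2.96 (camera, adjusted p = 2.25e-08, and adjusted p = 0.188 with an estimated correlation). Of 14 podocyte genes 10 rose, including Clic5 (6.01 ± 0.20, 64.5-fold), a cytoskeletal protein of foot processes, and Podxl (4.24 ± 0.24, 18.9-fold), while Cdkn1c, a cell cycle inhibitor, fell by 2.45. The podocyte median was 2.21 (adjusted p = 0.000913, and adjusted p = 0.324 with an estimated correlation). In the proximal tubule list 15 of 19 genes rose and Slc7a7 fell by 0.41. Aqp1, a water channel, rose 96.8-fold (6.60 ± 0.42), Hnf4a, a transcription factor of this segment, 49.1-fold (5.62 ± 0.43), and Pdzk1, a scaffold of the brush border, 25.9-fold (4.69 ± 0.37). This list had a median of 2.32 (adjusted p = 5.85e-05, and adjusted p = 0.324 with an estimated correlation), or 2.72 with slide as a block. When adjusted over the list alone, 15 rose and 2 fell. The loop of Henle and distal tubule list had 12 rising genes and a falling Ptger3 (-0.99) among 14, with a median of 2.85 (adjusted p = 6.59e-05, and adjusted p = 0.247 with an estimated correlation). Its examples were Irx1 (5.69 ± 0.27, 51.6-fold), a patterning factor, and Slc12a1 (4.68 ± 0.28, at least 5.93-fold), the salt transporter blocked by loop diuretics. The nephron progenitor list split, with 5 genes up, 5 down and 3 not past the test. Cited1 rose 7.03-fold (2.81 ± 0.23), Meox1 fell by 2.31, and Six2, which maintains the progenitor state, differed by 0.13 (adjusted p = 0.490). That list's median was 0.13 (adjusted p = 0.557).

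In the ureteric lineage 7 of 8 tip genes rose, such as Ret (2.47 ± 0.15, 5.54-fold), the receptor of the branching signal Gdnf, while its co-receptor Gfra1 fell by 0.42. Their median was 1.44 (adjusted p = 0.00123, and adjusted p = 0.188 with an estimated correlation). Among 19 stalk and collecting duct genes 17 rose, including Upk3a (7.28 ± 0.86, at least 42.7-fold), a urothelial plaque protein, Krt19 (6.13 ± 0.44, 69.8-fold) and the vasopressin receptor Avpr2 (5.10 ± 0.16, at least 8.41-fold). Calb1 (-0.70) and Hsd11b2 (-1.36) of this list fell, and its median was 2.41 (adjusted p = 2.72e-05, and adjusted p = 0.324 with an estimated correlation).

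Stromal genes changed in opposite directions. Of 10 cortical stromal progenitor genes 9 fell, led by Crabp1 and by Foxd1 (-3.33 ± 0.10, 10.1-fold), the defining transcription factor of these cells, and only Fibin rose (1.61). Their median was -1.81 (adjusted p = 0.00143, and adjusted p = 0.324 with an estimated correlation). All 13 genes of differentiated stroma and matrix rose, with a median of 3.63 (adjusted p = 2.25e-08, and adjusted p = 0.188 with an estimated correlation). Ogn, a matrix proteoglycan, rose 131-fold (7.04 ± 0.14), Penk, a marker of medullary stroma, 96.3-fold (6.59 ± 0.27), and Lox, which crosslinks collagen, 29.0-fold (4.86 ± 0.17). Smooth muscle genes rose in 7 of 10 cases, as with the contractile proteins Actg2 (7.09 ± 0.15, 136-fold), Cnn1 (5.48 ± 0.17, 44.7-fold) and Myh11 (5.12 ± 0.15, 34.9-fold), whereas renin (Ren1) differed by 0.25. The median of that list was 3.32 (adjusted p = 0.000289, and adjusted p = 0.280 with an estimated correlation). Among 13 endothelial genes 11 rose, including Cdh5, the vascular cadherin (4.52 ± 0.40, 23.0-fold), and Flt1 (4.46 ± 0.28, 22.0-fold), a receptor of vascular growth factor, while its other receptor Kdr fell by 1.06. The endothelial median was 3.21 (adjusted p = 0.000289, and adjusted p = 0.324 with an estimated correlation), or 2.89 with slide as a block.

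Markers of other cell types also moved. All 9 tested erythroid genes fell, with a median of -5.90 (adjusted p = 0.00118, and adjusted p = 0.324 with an estimated correlation), or -4.35 with slide as a block. The list call ended where only genes well above background on every array were kept (adjusted p = 0.186). Neuron and neural crest genes fell in 9 of 10 cases, as with Nefm (-5.10 ± 0.19, 34.3-fold), a neurofilament, and Stmn2 (-4.47 ± 0.21, 22.1-fold), a growth cone protein. Their median was -1.58 (adjusted p = 0.00738, and adjusted p = 0.188 with an estimated correlation). In the skeletal muscle list 8 of 11 genes fell and Acta1 rose (2.97 ± 0.15), while the list median of -1.82 missed the threshold (adjusted p = 0.0721). The myogenic factor Myog fell by 4.55 in that list. Macrophage genes split into 2 rising, 1 falling and 3 not past (median 0.27, adjusted p = 0.602), cartilage and bone into 4, 2 and 2 (0.98, adjusted p = 0.385), pluripotency genes into 2, 4 and 1 (-0.88, adjusted p = 0.557), and sex-linked genes into 0, 2 and 2 (-0.34, adjusted p = 0.401). Spp1, a bone and injury matrix protein, rose at least 66.9-fold (7.01 ± 0.34).

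All 14 genes of hypoxia and glycolysis rose, with a median of 2.74 (adjusted p = 1.38e-08, and adjusted p = 0.247 with an estimated correlation). Adm, a vasodilator peptide induced by low oxygen, rose by 5.32 ± 0.17, Egln3, an oxygen-sensing hydroxylase, 34.5-fold (5.11 ± 0.23), and Ndrg1 22.1-fold (4.47 ± 0.19). All 9 genes of tubular injury and inflammation rose, with a median of 3.35 (adjusted p = 7.32e-05, and adjusted p = 0.188 with an estimated correlation), among them Lcn2 (4.02 ± 0.12, 16.2-fold), the injury marker lipocalin, and Clu (3.75 ± 0.15, 13.4-fold). Each of 9 immediate early and heat shock genes rose (median 1.30, adjusted p = 0.000289, and adjusted p = 0.247 with an estimated correlation), as did each of 11 sterol synthesis genes (median 0.89, adjusted p = 3.97e-05, and adjusted p = 0.188 with an estimated correlation), such as Idi1 (1.39). Fatty acid oxidation genes split, with 3 up and 5 down of 11 (median -0.12, adjusted p = 0.716). The cell cycle list had 6 up and 4 down of 15, a median of -0.05 and a mean of 0.11, opposite in sign, with the test leaning up (adjusted p = 0.443). Posterior Hox genes mostly did not pass, with 1 up, 2 down and 5 not past (median -0.09, adjusted p = 0.677).

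For these changes slide and group overlapped in part. All day 7 arrays lay on slide 2, so with slide as a block each change rests on day 0 replicate 3 against them. The block and the comparison within slide 2 are therefore not separate checks. With slide as a block 4275 genes rose and 6490 fell. Within slide 2, which held 1 day 0 and 3 day 7 arrays, all 12354 called genes changed in the same direction. Those arrays also entered the calls, so this agreement was nearly built in. No list kept its call with an estimated correlation, and other groupings of the same 6 arrays into 3 and 3 gave 9 to 16 list calls against 16 for the real groups. Those groupings kept part of the day 7 change, so their list counts decide nothing. With genes near background set at their bounds, list medians fell for podocytes from 2.21 to 1.44, proximal tubule from 2.32 to 2.10, loop from 2.85 to 2.64, collecting duct from 2.41 to 2.04, smooth muscle from 3.32 to 2.35 and injury from 3.35 to 2.16. Those that were negative moved to -4.81 for erythroid, -1.57 for neuron and -1.48 for skeletal muscle genes. Simulated 2-fold changes in 100 genes were recovered for 71% and 4-fold changes for 96%, with 12 false calls among 17998 genes.

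**Figure D1:**
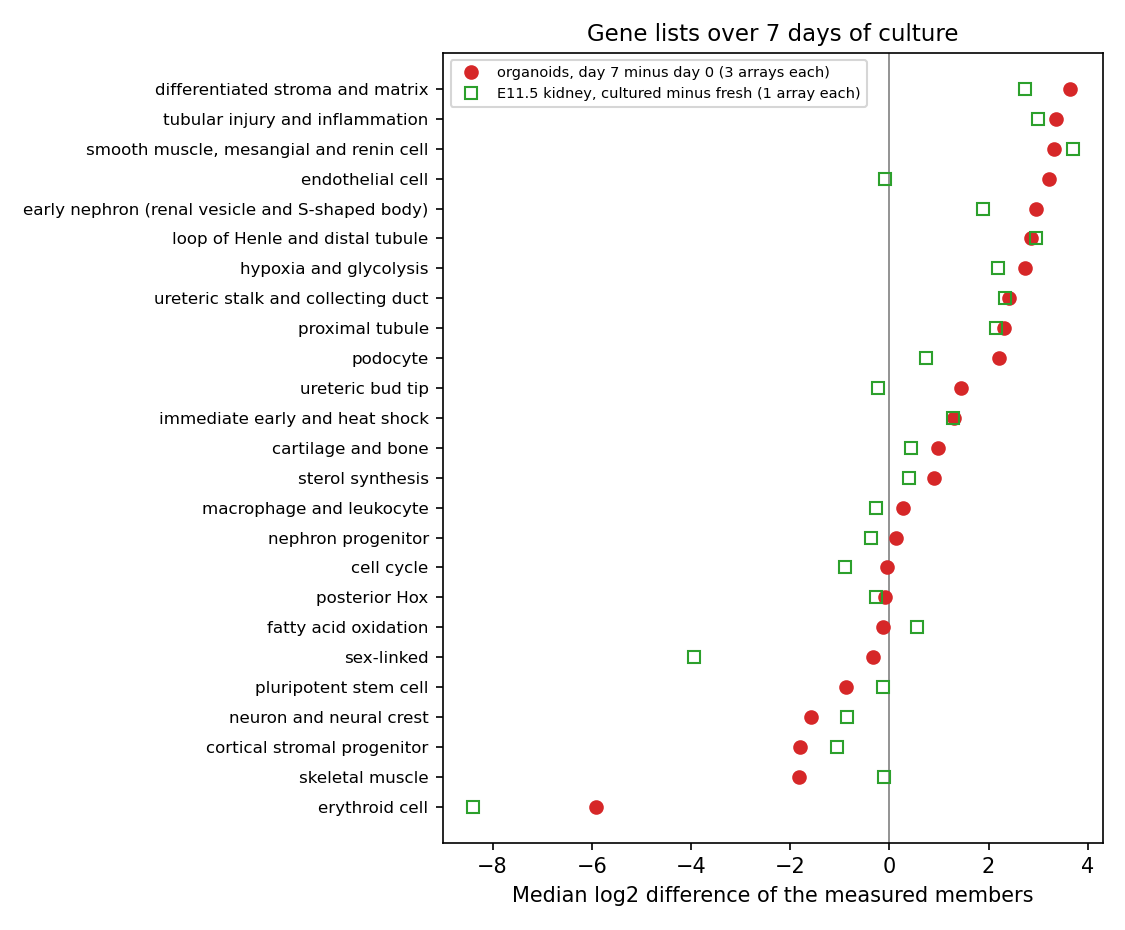
Median log2 change over 7 days of culture for the 25 preset gene lists. Red dots are day 7 minus day 0 organoids (3 arrays each) and green squares are cultured minus fresh E11.5 kidney (1 array each); differentiated stroma lies at 3.63 and 2.74, and the endothelial list at 3.21 and -0.09.

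How close uncultured organoids were to E11.5 kidney, the source of their stromal cells, was asked by comparing day 0 organoids (n = 3) with fresh E11.5 kidney (n = 1). Day 0 organoids had lower medians for lists of blood vessels, macrophages, branching ureteric tips and early nephrons, and higher ones for cortical stroma and smooth muscle. These calls rest on a preset correlation, and none held with an estimated correlation (adjusted p = 0.169 to 0.442 with an estimated correlation). Large excesses were seen for Myl1 (6.86 ± 0.94, at least 27.7-fold) and Myog (6.57 ± 0.84, at least 33.7-fold), a myosin light chain and a muscle-determining factor. The uncharacterised AA388235 (5.52 ± 0.20, at least 10.5-fold) and Kap (5.27 ± 0.77, at least 19.2-fold), an androgen-regulated proximal tubule gene, followed. Large deficits were seen for Cx3cr1 (-7.38 ± 2.06, at least 80.7-fold), a macrophage chemokine receptor, Krt23 (-6.86 ± 0.16, at least 26.8-fold), Mmrn1 (-6.86 ± 0.22, at least 29.4-fold), an endothelial secreted protein, the complement gene C1qc (-6.79 ± 2.01, at least 38.3-fold) and Cyth4 (-6.58 ± 1.66, at least 19.8-fold), a leukocyte gene. Cx3cr1, C1qc and Cyth4 lost their calls without any single day 0 array and with slide as a block, where their adjusted p-values were 0.0887, 0.0957 and 0.0689 (ranges over the alternatives 0.000451 to 0.0887, 0.00122 to 0.0958 and 0.000871 to 0.0689). Of 19581 genes tested, 3061 were higher and 2715 lower, or 2570 and 2457 with slide as a block and 578 and 1117 among the arrays of slide 1, where 16 of 101 genes followed here lost their calls, Pdgfra (adjusted p = 0.0528) and Aldh1a2 (adjusted p = 0.0651) among them.

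Among the lists, 11 of 13 endothelial genes were lower, including Flt1 (-4.94 ± 0.42, 30.7-fold) and Tie1 (-5.30), a vascular receptor, and Kdr alone was higher (0.50). The endothelial median was -4.14 (adjusted p = 5.93e-06, and adjusted p = 0.387 with an estimated correlation). Macrophage genes were lower in 8 of 12 cases, or 9 adjusted over the list alone, with a median of -3.11 (adjusted p = 0.000181, and adjusted p = 0.442 with an estimated correlation). Erythroid genes were lower in 5 of 11, or 7 adjusted over the list alone, with Hbb-bh1 (-6.45 ± 0.52, 87.5-fold) and Hba-x (-6.40 ± 0.14, 84.6-fold) as examples and a median of -4.21 (adjusted p = 6.15e-06, and adjusted p = 0.387 with an estimated correlation). Ureteric tip genes were lower in 7 of 8, as with Ret (-3.47 ± 0.22, 11.1-fold) and Etv4 (-1.89, 3.71-fold), a target of its signal, with a median of -1.72 (adjusted p = 6.15e-06, and adjusted p = 0.169 with an estimated correlation). Early nephron genes were lower in 9 of 13, as with Bmp2 (-3.24 ± 0.24, 9.42-fold), Ccnd1 (-2.60 ± 0.21, 6.06-fold) and Lhx1 (-2.37, 5.19-fold), and Osr2 was higher. Their median was -1.14 (adjusted p = 0.000282, and adjusted p = 0.271 with an estimated correlation). Cell cycle genes were lower in 14 of 16, such as Top2a (-1.62, 3.07-fold), with a median of -1.19 (adjusted p = 6.99e-09, and adjusted p = 0.324 with an estimated correlation). Hypoxia and glycolysis genes were lower in 9 of 14, such as Hk2 (-2.01, 4.03-fold), the first enzyme of glycolysis, with a median of -0.81 (adjusted p = 0.000213, and adjusted p = 0.442 with an estimated correlation). Sterol synthesis genes were lower in 7 of 11, such as Idi1 (-1.31), with a median of -0.63 (adjusted p = 0.00088, and adjusted p = 0.324 with an estimated correlation).

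Higher lists in day 0 organoids were fewer. Fatty acid oxidation genes were higher in 8 of 11, as with Cpt1a (2.09 ± 0.11, 4.26-fold), which carries fatty acids into mitochondria, and Pdk4 (1.99, 3.98-fold), with a median of 0.86 (adjusted p = 7.98e-05, and adjusted p = 0.169 with an estimated correlation). Cortical stromal progenitor genes were higher in 8 of 10, as with Pdgfra (1.05, 2.08-fold) and Aldh1a2 (1.02, 2.03-fold), the retinoic acid enzyme, with a median of 0.63 (adjusted p = 0.00452, and adjusted p = 0.425 with an estimated correlation). Smooth muscle genes were higher in 6 of 10, as with Acta2 (3.74 ± 0.19, 13.3-fold) and Cnn1 (2.14, 4.39-fold), with a median of 1.20 (adjusted p = 0.00343, and adjusted p = 0.425 with an estimated correlation). Skeletal muscle genes were higher in 5 of 11, as with Acta1 (3.94 ± 0.22), with a median of 1.25 (adjusted p = 0.0108, and adjusted p = 0.425 with an estimated correlation). The nephron progenitor list had 1 higher gene and 4 lower ones, led by Gdnf (-2.60 ± 0.18, 6.06-fold), with a median of -0.42 (adjusted p = 0.0494, and adjusted p = 0.492 with an estimated correlation). Of the immediate early genes Fos (3.29 ± 0.26, 9.76-fold) and Egr1 (2.05, 4.13-fold) were higher, with a list median of 0.04 (adjusted p = 0.282).

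Tubule genes need a measured value beside them in this comparison. The proximal tubule list had 7 genes higher, 1 lower and 11 not past (median 0.52, adjusted p = 0.160, or 0.0142 with slide as a block and 0.898 with an estimated correlation). Slc34a1 (4.70 ± 0.73), the phosphate transporter, and Kap were among the higher ones. Slc22a8, an organic anion transporter, was the lower one at -3.09 and turned to 0.08 with another background correction. The loop and distal tubule list had 1 higher and 1 lower of 14 (median 0.05, mean 0.45, the test leaning down, adjusted p = 0.993). For 46 genes that were low on the E11.5 array and high on the P0 array, day 0 replicates 1, 2 and 3 read a median of -7.63, -8.42 and -9.44 relative to P0, against -10.88 on the E11.5 array, which the choice of genes keeps low. With a P0-like signal subtracted from the day 0 arrays, an alternative added after the data were seen, the Kap difference was 3.48 (adjusted p = 0.0669, range over the alternatives 0.00275 to 0.0669).

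The remaining lists did not pass. Podocyte genes had 2 higher and 3 lower of 15 (median 0.53, adjusted p = 0.748), collecting duct genes 1 and 2 of 19 (-0.11, adjusted p = 0.748), and differentiated stroma genes 2 and 1 of 13 (0.21, adjusted p = 0.396). Neuron genes had 4 higher and 2 lower of 11, with a median of -0.10 and a mean of 0.06, opposite in sign (adjusted p = 0.993). Cartilage genes had 0 and 1 of 10 (median -0.06, mean 0.24, adjusted p = 0.985), pluripotency genes 1 and 1 of 7 (0.19, adjusted p = 0.748), injury genes 1 and 1 of 10 (0.14, adjusted p = 0.993), Hox genes 0 and 2 of 8 (-0.04, adjusted p = 0.619) and sex-linked genes 0 and 2 of 5 (-0.76, adjusted p = 0.0722). The single kidney array was assumed to vary like organoid replicates. The nephron progenitor call ended with slide as a block (adjusted p = 0.0655) and without day 0 replicate 2 (0.0650) or 3 (0.0652) or day 7 replicate 3 (0.0608), and with the P0-like signal subtracted (0.0527). Another background correction ended the calls of the cortical stromal (adjusted p = 0.128) and smooth muscle (adjusted p = 0.0570) lists. It raised the higher share of calls from 53.0% to 69.9% and the median of all genes from 0.04 to 0.17. With members at their bounds the smooth muscle and endothelial medians were 0.98 and -3.97. Keeping only genes well above background on every array ended the erythroid (adjusted p = 0.129) and skeletal muscle (adjusted p = 0.0773) calls. Simulated 2-fold changes were recovered for 44% of 100 genes and 4-fold ones for 75%, with 6 false calls among 19581 genes.

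**Figure D2:**
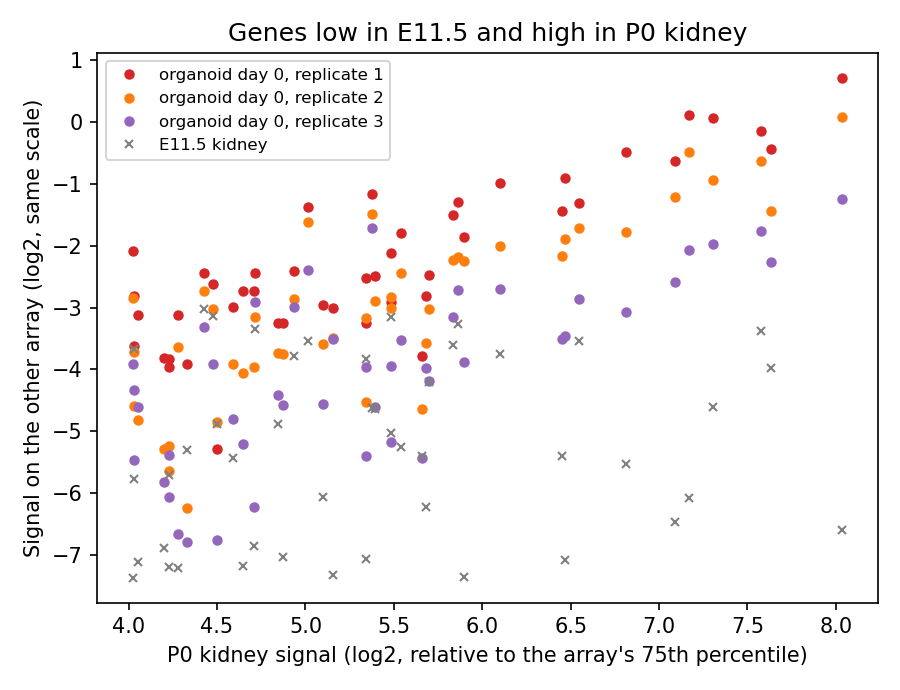
Signal of 46 genes that are low in E11.5 kidney and high in P0 kidney, each point 1 gene on 1 array. The x axis is the P0 log2 signal and the y axis the log2 signal on the 3 day 0 organoid arrays and the E11.5 array, with day 0 medians of -7.63, -8.42 and -9.44 below P0.

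Whether both tissues arrived at the same place was asked by comparing day 7 organoids (n = 3) with cultured E11.5 kidney (n = 1), which had the same 7 days of culture. Most tissue lists did not differ past the test, while in organoids those of contractile and matrix stroma had higher and those of macrophages and neurons lower medians. These calls rest on a preset correlation over all tested members of a list, of which 2 to 6 passed the limma test by gene. None held with an estimated correlation (adjusted p = 0.553 to 0.832 with an estimated correlation). Large excesses were seen for the Y-linked Ddx3y (6.40 ± 0.15, at least 20.3-fold) and Eif2s3y (4.99, at least 19.8-fold), with Gsdmc4 (5.86 ± 0.36, at least 15.2-fold), a gasdermin, AA388235 (5.42, at least 9.69-fold) and Zpld2 (5.15, at least 8.78-fold). The Y-linked excesses lay in the cultured kidney array, where Ddx3y read -6.89 and Eif2s3y -5.51. Fresh E11.5 kidney read 0.71 and -0.24, and day 7 organoids -0.49 and -0.52. Large deficits were seen for F13a1 (-6.95 ± 0.53, at least 38.6-fold), a clotting factor subunit of macrophages, Hbb-y (-6.36, at least 44.4-fold), Dbh (-5.64 ± 0.81), which makes noradrenaline, and the macrophage genes Fcna (-4.60, at least 6.77-fold) and Clec5a (-4.35, at least 4.39-fold). In total 678 genes were higher and 527 lower of 19581.

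Differentiated stroma genes were higher in 3 of 13 cases, as with Fbln5 (1.45) of elastic fibres, and in 11 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.000222, and adjusted p = 0.757 with an estimated correlation). Smooth muscle genes were higher in 6 of 10, such as Actg2 (2.16 ± 0.21, 4.46-fold) and Cnn1 (2.04, 4.12-fold), with a median of 0.94 (adjusted p = 0.0211, and adjusted p = 0.832 with an estimated correlation). Proximal tubule genes were higher in 3 of 19, such as Slc3a1 (1.86, 3.62-fold), an amino acid transporter subunit. Their median was 0.47 (adjusted p = 0.0196, and adjusted p = 0.832 with an estimated correlation), or 1.58 with slide as a block. Macrophage genes were lower in 3 of 12, such as Mrc1 (-4.30 ± 0.79), with a median of -2.62 (adjusted p = 0.000494, and adjusted p = 0.832 with an estimated correlation). Neuron genes were lower in 2 of 11, Elavl3 (-3.34, at least 2.55-fold) and Stmn2 (-2.78, 6.85-fold), with a median of -0.76 (adjusted p = 0.00448, and adjusted p = 0.553 with an estimated correlation). Erythroid genes were lower in 2 of 11 (median -1.22, adjusted p = 0.00475, and adjusted p = 0.832 with an estimated correlation), and with slide as a block their median was 0.06 (adjusted p = 0.536). Sex-linked genes had 2 higher and 1 lower of 5 (median 1.07, adjusted p = 0.0335, and adjusted p = 0.712 with an estimated correlation). Timp1 (2.23, 4.70-fold), an inhibitor of matrix proteases, and Comp (4.13, at least 4.69-fold), a cartilage matrix protein, were higher, while lipocalin Lcn2 was lower (-1.13).

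The nephron progenitor median was -0.18, with none of 13 past the limma test at an adjusted p under 0.05, early nephron 0.01, podocyte 0.60, ureteric tip -0.06 (mean 0.08), collecting duct -0.29, cortical stroma -0.13 and endothelium -0.40. For loop and distal tubule it was 0.31 (adjusted p = 0.832 with an estimated correlation), or 0.76 with slide as a block (adjusted p = 0.000343). Only day 0 organoids lay on both slides, so this block rests on day 0 replicate 3 against replicates 1 and 2. Kap moved from 1.34 to 3.23 with it, so shifts under this block carry differences among the day 0 arrays. The medians were 0.28 for skeletal muscle, -0.19 for cartilage (mean 0.56, the test leaning up), -0.52 for pluripotency, -0.16 for the cell cycle, 0.10 for hypoxia, 0.35 for immediate early genes, 0.07 for injury, 0.03 for Hox genes, 0.01 for sterol synthesis (mean -0.02, the test leaning down) and 0.18 for fatty acid oxidation. Such a missed threshold does not show that levels were equal, since simulated 2-fold changes were recovered for 39% of 100 genes and 4-fold ones for 80%, with 8 false calls among 19581 genes.

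The counts of this comparison were fragile. With slide as a block 98 genes were higher and 73 lower, and the calls of 24 of 103 genes followed here ended, Dbh, Actg2, Cnn1, Comp, Timp1, Fbln5, Stmn2, Lcn2, Slc3a1 and Mrc1 among them, while Ddx3y, Eif2s3y and F13a1 stayed past the threshold. The counts were 228 and 241 without day 7 replicate 1, 333 and 316 without replicate 2, and 270 and 237 without replicate 3, and 418 and 355 without day 0 replicate 1. Scaling to the median of each array raised the higher share from 56.3% to 76.3% of calls and the median of all genes from 0.01 to 0.20, and ended the calls of the proximal tubule, smooth muscle and sex-linked lists (adjusted p = 0.159, 0.142 and 0.159). Another background correction ended the erythroid (adjusted p = 0.0731) and sex-linked calls (adjusted p = 0.138). The latter was also lost without day 0 replicate 2 (0.129) or 3 (0.0822). Keeping only genes well above background on every array ended those of the erythroid (adjusted p = 0.331) and proximal tubule lists (adjusted p = 0.107).

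Organoids and E11.5 kidney were both cultured for 7 days, so the next question was whether the change differed between organoids and E11.5 kidney. By list median, the change in organoids was more positive than that in kidney for vessels, ureteric tips, early nephrons and dividing cells, and more negative for cortical stroma. These calls rest on a preset correlation, and none held with an estimated correlation (adjusted p = 0.223 to 0.435 with an estimated correlation). By construction, each difference of changes is the day 7 gap to cultured kidney less the day 0 gap to fresh E11.5 kidney. Medians at day 0 were -4.14 for vessels, -1.72 for tips, -1.14 for early nephrons, -1.19 for the cell cycle and 0.63 for cortical stroma. At day 7 they were -0.40, -0.06, 0.01, -0.16 and -0.13. These list differences thus lay mostly in the day 0 comparison and are not a separate result from it. Large positive differences were seen for Lrat (8.16 ± 0.62, at least 4.44), which stores vitamin A in esters, Zpld2 (7.57 ± 0.53, at least 3.94), Ddx3y (7.16 ± 0.21, at least 5.10), Rhd (7.11 ± 1.31, at least 5.91), a red cell membrane protein, and Glipr1 (6.66 ± 0.62, at least 5.37). Each had 1 or 2 groups below background, and the limits set those groups at the background. The Ddx3y difference lay mainly in the kidney arrays, at 0.71 fresh and -6.89 cultured, against -0.05 and -0.49 in day 0 and day 7 organoids. Cox8b, a muscle subunit of cytochrome oxidase, differed by -5.92 ± 0.47, or at least 4.79 below 0. Myog (-5.08 ± 1.19) and Olig3 (-4.95 ± 0.40), a neural transcription factor, also differed negatively, with no limit to be given because groups on both sides were near background. Mmp9 (-4.95 ± 0.42), a gelatinase, differed negatively too. For Mmp9 only fresh E11.5 kidney was below background on all its arrays, and no limit was given. The difference passed the test for 2813 genes, 1543 positive and 1270 negative. Of these, 1392 had mean changes of opposite sign in the 2 tissues. Another 965 had the same sign with the larger change in organoids, and 456 the same sign with the larger change in kidney. Neither change had to pass a test or a size limit for these counts, and the kidney change was 1 array against 1.

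By list, endothelial genes differed positively in 8 of 13 cases, or 11 adjusted over the list alone, as with Flt1 (4.52) and Tek (4.59), with a median of 3.55 (adjusted p = 3.50e-05, and adjusted p = 0.425 with an estimated correlation). Ureteric tip genes did so in 6 of 8, as with Ret (2.59) and Etv4 (2.14), with a median of 1.76 (adjusted p = 3.50e-05, and adjusted p = 0.223 with an estimated correlation). Early nephron genes did so in 7 of 13, or 10 adjusted over the list alone, as with Ccnd1 (2.22) and Wnt4 (2.10), with a median of 1.52 (adjusted p = 9.80e-05, and adjusted p = 0.240 with an estimated correlation). Cell cycle genes, whose medians were -0.05 over organoid culture and -0.90 over kidney culture, did so in 8 of 16, or 11 adjusted over the list alone, as with Top2a (1.65) and Mki67 (1.46), with a median of 0.93 (adjusted p = 4.68e-06, and adjusted p = 0.375 with an estimated correlation). Hypoxia genes did so in 5 of 14, as with Ankrd37 (2.13), with a median of 0.88 (adjusted p = 9.80e-05, and adjusted p = 0.447 with an estimated correlation), and sterol synthesis genes in 5 of 11 (median 0.70, adjusted p = 0.00251, and adjusted p = 0.320 with an estimated correlation). Erythroid genes did so in 4 of 11, as with Hba-x (4.64), with a median of 2.99 (adjusted p = 0.00403, and adjusted p = 0.572 with an estimated correlation), or 4.18 with slide as a block. Sex-linked genes did so in 2 of 5 (median 1.78, adjusted p = 0.00694, and adjusted p = 0.240 with an estimated correlation).

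Negative differences held for 5 of 10 cortical stromal genes, or 8 adjusted over the list alone, as with Pdgfra (-1.16), with a median of -0.77 (adjusted p = 0.00403, and adjusted p = 0.435 with an estimated correlation). They held for 4 of 11 skeletal muscle genes, with a median of -1.87 (adjusted p = 0.00694, and adjusted p = 0.425 with an estimated correlation), and for 4 of 11 fatty acid oxidation genes, as with Pdk4 (-2.02) and Cpt1a (-1.91), with a median of -0.58 (adjusted p = 0.00251, and adjusted p = 0.240 with an estimated correlation). Of neuron genes 4 of 11 differed negatively and 2 positively, as with Elavl3 (-4.34) and Nefm (-4.25), with a list median of -0.45 (adjusted p = 0.0743). Of the immediate early genes Fos differed by -3.43. The proximal tubule list did not pass (median -0.17, adjusted p = 0.957) and its sign was unstable. It was 0.21 with slide as a block (adjusted p = 0.508) and 0.78 with the P0-like signal subtracted from the day 0 arrays (adjusted p = 0.0259, range over the alternatives 0.0259 to 0.955). Medians of the other lists that did not pass were 0.07 for nephron progenitors, 0.26 for podocytes, 0.21 for loop and distal tubule (mean -0.15), 0.08 for collecting duct (mean -0.19), 0.28 for differentiated stroma, -0.37 for smooth muscle, 0.98 for macrophages, 0.09 for cartilage, -0.77 for pluripotency, 0.44 for immediate early genes (mean -0.45, the test leaning down), -0.22 for injury (mean 0.11, the test leaning up) and 0.17 for Hox genes. The counts were 1034 and 831 with slide as a block, 856 and 640 without day 7 replicate 1, and 825 and 594 without day 7 replicate 3. Myog missed the threshold with slide as a block (adjusted p = 0.0937, range over the alternatives 0.00049 to 0.0937) and without any single day 0 array. Rhd missed it without day 7 replicate 1 (adjusted p = 0.0539, range 0.000233 to 0.0539). Another background correction gave 2870 and 5639, with a positive share of 33.7% and a median of all genes of -0.14 in place of -0.04. It ended the cortical stromal (adjusted p = 0.0662) and sex-linked (adjusted p = 0.202) calls, and the sex-linked median became -0.12. Keeping only genes well above background on every array ended the erythroid call (adjusted p = 0.490), and keeping all genes ended that of skeletal muscle (adjusted p = 0.0569). Scaling to the median gave a positive share of 66.2% in place of 54.9%. Simulated 2-fold and 4-fold differences were recovered for 6% and 55% of 100 genes, with 2 false calls among 19581 genes.

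Cultured and fresh E11.5 kidney were compared as 1 array each, without a test, and they differed in Y-linked genes as well as in culture. Cultured kidney was higher by 8.16 for S100g (286-fold), a calcium-binding protein of the distal tubule, and by 7.75 for Fxyd4 (215-fold), a collecting duct regulator of the sodium pump. Actg2 was 112-fold and Penk 108-fold higher. These sizes depend on the background correction, since with normexp 60 of 85 genes followed moved by at least 1 SD of organoid replicates, S100g to 5.29 and Fxyd4 to 6.44. Large deficits were seen for globins, Hbb-bh1 (-9.37), Hbb-y (-8.43), Hbb-b2 (-8.40), Hba-a1 (-8.39) and Hbb-bt (-8.13). At least 2-fold differences were counted for 2427 higher and 1665 lower genes of 19422. Of the lists, 7 of 9 measured smooth muscle genes, 12 of 13 differentiated stroma genes, 7 of 10 injury genes and 9 of 14 loop and distal tubule genes were at least 2-fold higher, with medians of 3.69, 2.74 and 2.95 for smooth muscle, stroma and loop. Collecting duct (12 of 19, median 2.33), hypoxia (10 of 14, 2.19), proximal tubule (14 of 19, 2.15), early nephron (10 of 13, 1.88), immediate early (6 of 9, 1.28) and podocyte genes (7 of 15, 0.74) lay in the same direction. All of these lists were above 99% of 10000 random lists of matched signal. Erythroid (median -8.39, 11 of 11 at least 2-fold lower), cortical stromal (-1.06, 5 of 10), sex-linked (-3.94, 4 of 5) and cell cycle genes (-0.90, 6 of 16) and neuron genes (-0.85, 3 of 11) were below 99% of them, and endothelial genes (median -0.09, 2 of 13 at least 2-fold lower) were not. The Y-linked Ddx3y and Eif2s3y differed by -7.60 and -5.27, at least 46.4-fold and 24.1-fold.

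The fresh stages show how the kidney itself changes from E11.5 to P0. Proximal tubule genes rose and embryonic globins fell among the genes named here. Slopes per stage were 3.57 ± 0.52 for Slc17a1 (at least 1366-fold from E11.5 to P0), a phosphate transporter, 3.54 ± 0.62 for Mep1b (at least 1202-fold) and 3.44 ± 0.58 for Mep1a (at least 2981-fold), the brush border meprins, and 3.52 ± 0.47 for Slc34a1. Spp2 (3.42 ± 0.43, at least 3786-fold), Slc22a19 (3.39 ± 0.48, at least 845-fold), an organic anion transporter, and Hsd3b4 (3.34 ± 0.55, at least 4588-fold), a steroid dehydrogenase, rose too. Where a fold is given as at least a value, 1 end of the slope was below background, so the slope itself is uncertain. Slc34a1 has no such limit, but its E11.5 value of -7.36 was as low as that of Mep1b (-7.32), so its slope is uncertain too. Falling slopes were seen for Hbb-y (-3.74 ± 0.42), Hba-x (-3.48 ± 0.19, at least 2837-fold), Hbb-bh1 (-2.51 ± 0.36, 772-fold) and Arg1 (-1.98 ± 0.24, at least 77.1-fold), the arginase. The growth regulators Lin28b (-1.62 ± 0.07) and Hmga2 (-1.44 ± 0.08), Slitrk5 (-1.44 ± 0.24, with P0 below background) and Chl1 (-1.42 ± 0.17) fell as well. Of 20789 genes, 2370 rose and 2734 fell with stage (adjusted p under 0.05), while 1937 (9.32%) rose and 1998 (9.61%) fell at all 4 steps, where a random order gives 0.833% each way.

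By list, 18 of 20 proximal tubule genes rose, with a median slope of 2.33 (adjusted p = 1.81e-12, and adjusted p = 0.257 with an estimated correlation). Loop and distal tubule genes rose in 11 of 16, or 15 adjusted over the list alone, as with Umod (2.70), the most abundant urinary protein, with a median of 1.57 (adjusted p = 1.68e-09, and adjusted p = 0.257 with an estimated correlation). Collecting duct genes rose in 14 of 20, as with the water channels Aqp3 (1.57, 53.2-fold from E11.5 to P0) and Aqp2 (1.53, 41.4-fold), with a median of 0.95 (adjusted p = 3.34e-08, and adjusted p = 0.257 with an estimated correlation). Fatty acid oxidation genes rose in 8 of 11, as with Acadm (0.95), a dehydrogenase of medium chains, with a median of 0.50 (adjusted p = 9.09e-07, and adjusted p = 0.257 with an estimated correlation). Podocyte genes rose in 8 and fell in 2 of 15 (median 0.49, adjusted p = 0.000432, and adjusted p = 0.462 with an estimated correlation), smooth muscle genes rose in 6 and fell in 1 of 9, as with Ren1 (1.65, 46.6-fold) and Acta2 (1.43, 41.9-fold) (median 1.02, adjusted p = 0.00144, and adjusted p = 0.442 with an estimated correlation). Differentiated stroma genes rose in 4 of 13, as with Penk (84.5-fold from E11.5 to P0) (median 0.48, adjusted p = 0.00134, and adjusted p = 0.493 with an estimated correlation), and endothelial genes in 3 of 13 (median 0.21, adjusted p = 0.00142, and adjusted p = 0.548 with an estimated correlation).

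Falling lists were those of progenitors, tips, neurons and dividing cells. Nephron progenitor genes fell in 8 of 13, as with Osr1 (-0.90) and Six2 (-0.59) (median -0.45, adjusted p = 0.00466, and adjusted p = 0.442 with an estimated correlation). Ureteric tip genes fell in 6 of 8, as with Sox8 (-0.73) and Ret (-0.38) (median -0.36, adjusted p = 0.00727, and adjusted p = 0.493 with an estimated correlation), and cortical stromal genes in 5 of 10, as with Foxd1 (-1.03, 16.8-fold) (median -0.37, adjusted p = 0.00139, and adjusted p = 0.257 with an estimated correlation). Neuron genes fell in 7 of 11, as with Nefm (-1.40) (median -0.64, adjusted p = 0.000394, and adjusted p = 0.338 with an estimated correlation). Cell cycle genes fell in 8 of 16, or 14 adjusted over the list alone (median -0.37, adjusted p = 0.000308, and adjusted p = 0.548 with an estimated correlation), and posterior Hox genes in 4 of 8 (median -0.26, adjusted p = 0.0277, and adjusted p = 0.442 with an estimated correlation). The erythroid list fell in 3 of 11 (median -0.21, adjusted p = 0.0813). Lists without a call were early nephron (median 0.32, adjusted p = 0.0820), macrophage (-0.01, mean 0.05, the test leaning up, adjusted p = 0.331), skeletal muscle (-0.18, adjusted p = 0.232), cartilage (-0.06, mean 0.06, adjusted p = 0.956), pluripotency (0.04, adjusted p = 0.255), hypoxia (-0.08, mean 0.08, adjusted p = 0.956), immediate early (0.07, adjusted p = 0.211), injury (0.23, adjusted p = 0.0601), sterol synthesis (-0.18, adjusted p = 0.0846) and sex-linked genes (0.13, mean -0.16, adjusted p = 0.622).

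These slopes rest on 1 array per stage and leaned on the later ones. The counts were 304 rising and 71 falling without P0, 625 and 244 without E17.5, 1610 and 770 without E15.5, 1815 and 1702 without E13.5, and 2062 and 3910 without E11.5, and of 106 genes followed 63 lost their calls without P0 and 49 without E17.5. Without E11.5 the differentiated stroma, endothelial and Hox lists lost theirs (adjusted p = 0.0560, 0.107 and 0.141). Scaling to the median raised the rising share of calls from 46.4% to 64.9%. Simulated slopes of 0.5 and 1 were recovered for 40% and 74% of 100 genes, with 11 false calls among 20789 genes.

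Between neighbouring stages, compared as 1 array each without a test, the second step was the largest for the proximal tubule list. From E11.5 to E13.5, Fxyd4 (5.63), Hes5 (5.48), Ogn (5.05) and Irx1 (4.70) were higher, and Gdf5 (-4.25), Dnm3os (-3.45), Insm1 (-3.40) and Dbh (-3.38) lower. From E13.5 to E15.5, Spp2 (7.22, 149-fold), Slc34a1 (6.77, 109-fold), Kcnj1 (6.50), a potassium channel of the loop, Cyp2d26 (6.46) and Upk3a (6.17) were higher, and Hbb-y (-4.56), Hbb-bh1 (-4.45), Hba-x (-3.68), the histone gene H4c4 (-3.44) and Ptx4 (-3.32) lower. From E15.5 to E17.5, Kap (7.37, 166-fold), Serpina6 (5.14), Acsm1 (5.03), Acox2 (4.41) and Them7 (4.25) were higher, and Hbb-y (-5.37), Hba-x (-4.09), Prim2 (-4.06), Unc93a2 (-3.03) and Nlrp3 (-2.70) lower. From E17.5 to P0, Wnt10a (5.45), Cyp4a14 (5.18), Ptprr (4.75), H2-Q1 (4.41) and Clec2h (4.41) were higher, and H4c4 (-4.97), H4f16 (-4.73), Kif5b (-4.65), Hbb-b2 (-3.85) and H4c14 (-3.83) lower. With normexp background correction 40 of 60, 37 of 52, 28 of 47 and 18 of 46 genes followed over these steps moved by at least 1 SD of organoid replicates. At least 2-fold differences numbered 1135 higher and 1461 lower, then 1853 and 342, then 1086 and 495, then 860 and 697. Proximal tubule medians over the 4 steps were 0.68, 3.61, 2.08 and 1.40. Scaling to the median moved the median of all genes from 0.07 to 0.37 in the first step and from -0.12 to -0.40 in the second. It moved the higher share of these genes from 43.7% to 62.3% and from 84.4% to 64.9%.

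Maturity was read from the position of each array on the axis from E11.5 (0) to P0 (1) over 20783 genes. E13.5, E15.5 and E17.5 kidney lay at 0.266, 0.576 and 0.791. Day 0 organoids lay at 0.134 ± 0.0301 and day 7 organoids at 0.548 ± 0.00625 (SD, n = 3 each), and cultured kidney lay at 0.484. The organoid difference of 0.414 had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 arrays can give. By root mean square difference the nearest stage was E11.5 for each day 0 array and E15.5 for each day 7 array and for cultured kidney. The nearest stage was not close, since day 7 organoids lay on average 0.983 from E15.5 kidney, and E13.5 kidney lay 0.865 from it. Likewise, day 0 organoids lay on average 0.929 from E11.5 kidney, and E13.5 kidney lay 0.877 from it.

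**Figure D3:**
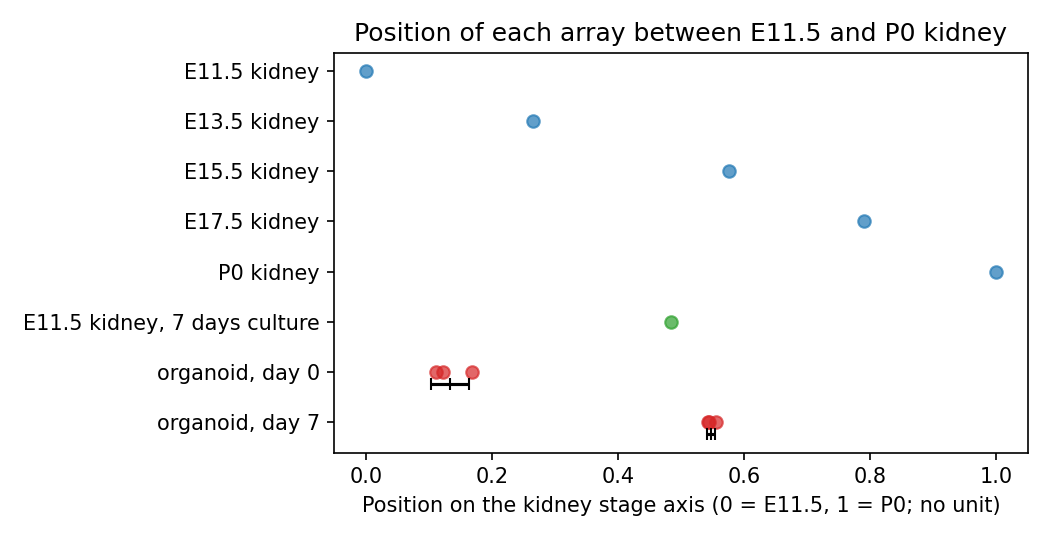
Position of each of the 12 arrays on the E11.5 to P0 axis, each point 1 array and black bars the mean ± SD of the organoid groups. Day 0 organoids sit at 0.134 and day 7 organoids at 0.548, between E13.5 (0.266) and E15.5 (0.576) kidney for the latter.

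Across 20958 genes, which are not independent replicates, the organoid change over culture correlated with the change from E11.5 to P0 (Pearson's r = 0.545, Spearman's rho = 0.413) and with the change of cultured kidney (r = 0.668, rho = 0.538). The change of cultured kidney correlated with the change from E13.5 to P0 (r = 0.492, rho = 0.487). Of 2048 genes that rose with stage and were tested in organoids, 1532 rose there too, where 560 would be expected if the calls were independent, and of 2601 that fell, 1801 fell in organoids, where 1072 would be expected.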

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

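The tests of slide differences, the test of genes above background on every array, the 3 tests of newborn kidney genes and the test of endothelial growth were chosen only after the results were seen, and the others before.

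A difference between groups set apart 1543 genes with a more positive and 1270 with a more negative 7-day change in organoids than in E11.5 kidney. By gene the differences were 8.16 for Lrat (at least 4.44 with groups below background set at the background), 7.57 for Zpld2 (at least 3.94), 7.16 for Ddx3y (at least 5.10), 7.11 for Rhd (at least 5.91) and 6.66 for Glipr1 (at least 5.37). They were -5.92 for Cox8b (limit -4.79), and -5.08 for Myog, -4.95 for Olig3 and -4.95 for Mmp9 without a limit, so these sizes are uncertain. By list the medians were 3.55 for endothelium, 2.99 for erythroid, 1.78 for sex-linked, 1.76 for ureteric tip, 1.52 for early nephron, 0.93 for cell cycle, 0.88 for hypoxia and 0.70 for sterol synthesis genes. They were -1.87 for skeletal muscle, -0.77 for cortical stroma and -0.58 for fatty acid oxidation genes. For endothelium, ureteric tip, early nephron and cell cycle these lay mostly in day 0 organoids against E11.5 kidney (medians -4.14, -1.72, -1.14 and -1.19). Ddx3y read 0.71 in fresh and -6.89 in cultured kidney, which differed in Y-linked genes as well as in culture. Probes without a gene name were signal that no comparison used: of 6884 tested, 1002 were higher and 2709 lower at day 7.

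Of the genes called between day 7 and day 0, 96.1% kept at least 50% of their change within slide 2, which rests on 1 day 0 array. That array and the day 7 arrays also entered the calls, so genes on which it disagreed were seldom called. The share therefore cannot decide on a slide difference. Of the 4500 brightest genes 63.6% were called, against 68.6% of all, and of genes well above background on every array 69.9% were called. This argues against low day 0 signal as the whole cause, while a part in dim genes stays open. Of 10 splits of the 6 arrays into 3 and 3, only the real one (1) gave 12354 calls, the highest other gave 0, and 10 splits are too few for a share under 0.05. For the lists 2 splits gave 16 calls, the real one and 1 other. The other splits held unequal numbers of day 7 arrays on their sides and so kept part of the real change. Their list counts therefore cannot decide whether the list calls set the real groups apart.

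Genes of newborn kidney on the day 0 arrays were weighed among 46 genes, after a first plan to use unnamed probes left only 2. Their difference from P0 had an interquartile range of at most 1.07 on each day 0 array, as dilute RNA of late kidney would give. Their correlation with P0 exceeded that with cultured kidney by at least 0.228, which argues against tubule cells like those of cultured kidney. Day 0 replicate 3, on the slide without kidney, had 17.4 points more of these genes well above background than E11.5 kidney. The genes were chosen for low E11.5 signal, so this value decides nothing and signal from neighbouring arrays stays open. A biological source in the organoids was not tested further.

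Endothelial genes rose in organoids by a median of 2.89 within slide 2, which argues against a slide difference but rests on day 0 replicate 3 alone. Their median change was above 100% of random lists matched on E11.5 signal, which argues against low day 0 signal. Day 7 organoids differed from cultured kidney by -0.40, and 9 of 13 members were already well above background at day 0. Growth of endothelial cells brought in with embryonic stroma therefore stays open.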

How the results depend on the processing

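Slide as a block in comparisons with kidney, single slides and the P0-like subtraction were alternatives chosen only after results were seen. Of the values followed, 8472 for named genes and 1817 for lists stayed on the same side of the threshold, or without a test shifted by under 1 SD of organoid replicates. Where there was a test, direction was compared only if the main value or the alternative passed the threshold, and for lists by the test. Pairs of 1 array were compared by sign alone. For genes 470 lost and 223 gained a call, and 15 changed direction, 13 past the threshold in at least 1 setting and 2 without a test. Of pairs of 1 array, which had no test, 251 values moved by at least 1 SD. With normexp correction such shifts made up 60 of 85 in cultured kidney and 40 of 60, 37 of 52, 28 of 47 and 18 of 46 over the 4 steps. For lists 88 lost a call, 61 of them with an estimated correlation, 41 gained one and 1 changed direction by the test. List medians changed sign in 72 cases past the threshold in neither setting and in 4 past it in at least 1. The 4 were the erythroid list of day 7 organoids against cultured kidney (0.06 with slide as a block), the sex-linked list of the difference of changes (-0.12 with normexp), the macrophage trend (0.11 without E11.5) and the proximal tubule list below. Values of named genes past the threshold in neither setting changed sign in 26 cases. The position of day 7 minus day 0 organoids ranged from 0.375 to 0.485, and that of cultured kidney minus day 7 from -0.0796 to -0.0606. Lower signal limits the day 0 arrays, with 50.6% to 54.3% of probes well above background.

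With an estimated correlation 0 lists were higher and 0 lower between day 7 and day 0, and the cause was not tested.

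Normexp correction with an offset of 50, for which the cause was not tested, gave 8028 higher genes in day 0 organoids against E11.5 kidney, 1816 higher and 1346 lower in day 7 organoids against cultured kidney, 2870 and 5639 for the difference of changes, and 4264 falling with stage. At 2-fold it gave 362 higher and 315 lower from E11.5 to E13.5, 470 and 63 to E15.5, 396 and 56 to E17.5, 322 and 77 to P0, and 1172 and 538 in cultured kidney. Correlations became 0.521 (organoid with stages), 0.692 (organoid with cultured kidney) and 0.548 (cultured kidney with stages). Against E11.5 kidney, Comp (0.35), Lfng (0.0926), Car9 (0.00498), Bsnd (0.35), Slc22a8 (0.0839), Kdm5d (0.45), Uty (0.21) and Icam1 (0.32) turned positive in day 0 organoids. Lfng (-0.14) and Icam1 (-0.0204) turned in the difference of changes, and Ibsp (-0.0299) from E13.5 to E15.5.

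Scaling to the median, where the cause was not tested, gave 1125 higher and 349 lower for day 7 organoids against cultured kidney, 765 negative differences of changes, 946 genes falling with stage, 1786 higher from E11.5 to E13.5 and 784 lower to E15.5.

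Without a background filter more genes entered, and 11879 fell between day 0 and day 7, 6072 were higher in day 0 organoids, 401 higher in day 7 organoids against cultured kidney and 1782 fell with stage. At 2-fold 724 were lower from E13.5 to E15.5, 937 lower to E17.5, and 1346 higher and 1285 lower to P0. Correlations were 0.522, 0.597 and 0.459. With signal well above background on every array fewer genes were tested, and 749 higher and 760 lower were left from E11.5 to E13.5, 973 and 204 to E15.5, 205 lower to E17.5, 278 lower to P0 and 1044 lower in cultured kidney. Correlations were then 0.572, 0.730 and 0.553.

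Averaging probes turned Hoxd11 to -0.0584 between day 7 and day 0, Tdgf1 to 0.44 in day 0 organoids against E11.5 kidney and Esrrb to -0.79 from E17.5 to P0, and the cause was not tested. Moderation with trend and robust settings gave 1271 higher and 919 lower genes in day 7 organoids against cultured kidney, and the cause was not tested.

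A threshold of 2-fold, which by construction leaves fewer genes, gave 2833 and 1654 between day 7 and day 0, 849 and 1482 for day 0 organoids against E11.5 kidney, 358 higher for day 7 organoids against cultured kidney and 816 negative differences of changes. A threshold of 3-fold gave 577 and 827, 1090 and 153, 548 and 225, and 381 and 313 over the 4 steps, and 1511 and 675 in cultured kidney.

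With slide as a block 98 genes were higher and 73 lower in day 7 organoids against cultured kidney, and 831 differences of changes were negative. On slide 1 alone, with fewer arrays, 578 were higher and 1117 lower in day 0 organoids. With a P0-like signal subtracted from the day 0 arrays, the proximal tubule median of the difference of changes turned from -0.17 to 0.78, and with slide as a block to 0.21. The cause was not tested, but the block for slide rests on day 0 replicate 3 against replicates 1 and 2.

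Leaving out 1 array, with fewer samples, gave 228 to 784 higher and 237 to 623 lower for day 7 organoids against cultured kidney (418 higher without day 0 replicate 1, 228 and 241 without day 7 replicate 1, 333 and 316 without replicate 2, 270 and 237 without replicate 3). The difference of changes ranged from 825 to 1521 and from 594 to 1275 (856 and 640 without day 7 replicate 1, 825 and 594 without replicate 3). The trend ranged from 304 to 2062 rising and 71 to 3910 falling (1702 falling without E13.5, 770 without E15.5, 625 and 244 without E17.5, 304 and 71 without P0). The slope of Hes5 ranged from -0.68 to 1.24.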

Other observations

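Tests of this part were chosen before the results were seen.

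Genes of the early nephron and of neurons differed in opposite directions between E11.5 and E13.5. Of 13 early nephron genes 11 were at least 2-fold higher, with a median of 1.78, and of 11 neuron genes 7 were at least 2-fold lower, with a median of -1.46. Between E17.5 and P0, 7 of 10 measured erythroid genes were at least 2-fold lower, with a median of -2.65. Hypoxia genes had a median of 2.74 over organoid culture and 2.19 over kidney culture, and a median slope of -0.08 over the fresh stages, although Ndrg1 had a slope of 1.46. In cultured against fresh E11.5 kidney Xist differed by 0.38, beside -7.60 for Ddx3y and -5.27 for Eif2s3y.

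Some housekeeping genes had large differences between neighbouring stages, 1 array each. Prim2 read -4.06 from E15.5 to E17.5 and Kif5b -4.65 from E17.5 to P0. The histone gene H4c4 read -3.44 from E13.5 to E15.5 and -4.97 from E17.5 to P0, where H4f16 read -4.73 and H4c14 -3.83. Between these falls H4c4 rose, from 4.10 at E15.5 to 8.03 at E17.5, so its values did not fall steadily with stage.

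The order of the stages was tested by fitting the trend to each of 60 orders of the 5 arrays, mirrors counted as 1. Only 1 order, the real one, gave 5104 calls, so a chance order would seldom give this count. The highest other, with E11.5 and E13.5 exchanged, gave 4104. The count therefore says little on the order of E11.5 and E13.5.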
